A study of Homo sapiens with 10 samples.

How the data were processed

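Biopsies of human aorta in 3 classes of stiffness (stiff, medium, distensible) were profiled on 1-colour short-oligonucleotide arrays, 1 array per sample. The deposited table holds 1 linear intensity per probe set and sample, for 12625 probe sets including 67 control probe sets. The scanner program, the summary method and the scaling target are not given in the sources used here. The deposited intensity values can be negative, as differences between perfect-match and mismatch probes can be, and the authors' values share a 2%-trimmed mean (largest over smallest 1.00016), so they were taken as already scaled between arrays. Nothing in the labels says that the samples of a class came from separate people, so the p-values measure only the spread between these samples, which may be technical.

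Classes came from the sample labels alone, and replicate numbers follow the order of deposit and pair nothing. All pairs of samples were compared before any were averaged. The values of stiff replicate 1 and medium replicate 1 were identical, so 9 distinct arrays stand behind the 10 samples, and the values cannot tell which label is right. The design, the gene lists and the rule for named genes were fixed before the data were examined, and the design fitted all 10 samples. The main results depart from it: this array was left out and 8 arrays were fitted (3 stiff, 1 medium, 4 distensible). The fit as first designed, and the array counted once as stiff or once as medium, were run as alternatives added after the data were seen. The titles of stiff replicates 1 and 4 differ only by a capital letter; the SD of their log2 difference was 1.11 against 0.741 for the rule that would have made them 1 replicate, so they were treated as different arrays.

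Values under a floor, the median over arrays of each array's 30th percentile (151 intensity units, log2 7.24), were set to the floor, and log2 was taken. A fold against a group that lies wholly at the floor is written "at least", which is a bound with respect to this floor only. The floor lies below the noise, the root mean square of the values below 0 (mean 2304 intensity units on stiff and 2764 on distensible arrays). The true fold may therefore be smaller. Probe sets above the floor on at least 4 arrays were tested, controls aside, which left 9270. Limma 3.58.1 in R 4.3.3 was used with 1 mean per class (lmFit and eBayes, all 8 arrays in 1 fit so that the classes share 1 estimate of the spread), two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. The trend used a slope on class scores of 0, 1 and 2. Values of single arrays and of list scores were compared with exact permutation tests over the 35 splits of the 7 stiff and distensible arrays. Plots were drawn with Matplotlib 3.10.9.

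Gene names came from the platform annotation supplied with the table, with symbols updated by gene identifier through a RefSeq gene table of assembly GRCh38.p14. Of the probe sets, 10961 had 1 symbol, 545 several and 1119 were not listed there; 10949 symbols were updated and 12 kept. No probe set with several symbols was named, and no coordinates are given since the build behind the annotation is not given in the sources used here. XIST and Y-linked genes were not named. A gene with several probe sets was represented in the gene lists by its brightest tested one, which gave 6576 genes.

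The 34 gene lists (1021 genes, 833 of them on the array) cover matrix, contractile, signalling, stress and housekeeping genes and markers of cell types that an aortic biopsy could hold, and were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry stood beside it. The adjustment covers all 34 lists, of which 33 are described. Per direction of stiff against distensible, the rule for named genes took the 12 genes with the largest fold among those past the threshold, filled up with the smallest p among probe sets whose classes did not overlap. It took the 5 genes with the smallest p per direction of the trend and each medium comparison, and up to 4 members of a list.

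Alternatives covered quantile and median scaling, the floor, the filter, the variance model, array weights, the arrays in the fit, averaging of stiff replicates 1 and 4, and each array left out in turn. An asinh scale without a floor was added after the data were seen. The method was tested on simulated data for stiff against distensible aorta, in 20 simulations with 200 of 9270 probe sets changed. The changed probe sets were drawn from those with a mean log2 value above the median. The recoveries therefore do not cover dim probe sets near the floor. Changes of 1, 2 and 4 log2 units were recovered in 0.448%, 35.8% and 82.2% of cases, and 7.59% of the calls were false, against 6.17% without the floor. A list of interferon genes shifted by 1 log2 unit among 6576 genes was called in all 20 simulations with independent genes, with 1 other list called over all of them.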

Results

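Gene expression was measured in biopsies of human aorta with 1-colour short-oligonucleotide arrays. The labels sort the biopsies into 3 classes of arterial stiffness. They give no values of pulse wave velocity, the speed at which the pressure wave travels along an artery, which is higher in a stiffer vessel. As deposited there were 4 stiff, 2 medium and 4 distensible samples. The comparisons ask which genes and groups of genes differ between stiff and distensible aorta, and where the medium class lies. Of the 45 pairs of samples, 1 pair held identical values at every probe set, and its members carry different class labels (stiff replicate 1 and medium replicate 1). In no other pair were more than 0.0158% of the values equal. Because this array cannot belong to both classes, it was left out of the main comparisons, and 3 stiff, 1 medium and 4 distensible arrays remained. The 2%-trimmed mean lay between 2502 and 2503 intensity units on every array, and 22.6% to 31.8% of an array's values were 0 or below. For arrays, their number limits the precision, and the median standard error (SE) of a log2 difference between stiff and distensible aorta was 0.64.

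Between stiff and distensible aorta, 1 gene passed the test. KIF17, which encodes a kinesin motor of dendrites and cilia, was at the floor of the measurement (log2 7.24) on all 3 stiff arrays, against a mean log2 value of 11.60 ± 0.30 (SD, n = 4) on the distensible arrays. With this floor it was at least 20.6-fold lower in stiff aorta (log2 difference −4.36 ± 0.34 SE, limma adjusted p = 0.0224). No gene passed in the other direction. Leaving out any 1 of stiff replicates 2, 3 and 4 or distensible replicates 1, 2, 3 and 4 ended the KIF17 call, with adjusted p from 0.0743 to 0.278 although the log2 difference stayed between −4.23 and −4.47, and so did a scale without a floor (adjusted p = 0.968) and the fit of all 10 samples under their deposited labels (adjusted p = 0.579). Some settings changed the size of the difference as well: it was −1.67 with the floor at the 50th percentile and −3.45 with all 10 samples. Apart from leaving out each array in turn there were 12 alternatives, of which 6 ended the KIF17 call and 6 kept it. Among the latter was the array under 2 classes counted as medium (limma adjusted p = 0.00323). Another was the fit of only the 2 classes compared. It had to repeat the main result, since the 1 medium array adds nothing to the estimated spread, and is no separate support.

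The other genes named here did not pass and are those with the smallest p among genes whose stiff and distensible values did not overlap. On the higher side stood MYT1, a zinc finger transcription factor of neural cells, at 11.15 ± 0.52 (SD, n = 3) in stiff against 7.52 ± 0.56 (SD, n = 4) in distensible aorta (adjusted p = 0.211). A probe set of COMP, the cartilage oligomeric matrix protein, had means of 12.69 ± 0.45 and 10.53 ± 0.61 in the same order (adjusted p = 0.621), while a brighter one differed by 0.36 ± 0.77 SE, and the chemokine CCL25 had means of 10.54 ± 0.15 and 7.96 ± 0.91. A probe set of the growth factor IGF1 was at the floor on all 4 distensible arrays and at least 4.21-fold higher in stiff aorta (adjusted p = 0.375), but another IGF1 probe set had the opposite sign (−1.64 ± 0.86 SE). MAD2L1, a spindle checkpoint gene, was at least 5.29-fold higher, and the mitochondrial thiolase gene ACAT1 at least 4.11-fold higher, likewise against distensible arrays at the floor. ZNF174 was at least 3.90-fold higher in the same sense. MRPS12, PCDH9, VAPB, ZKSCAN8 and PTPRD filled the list, with log2 differences from 2.06 to 3.18.

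On the lower side, a probe set of MET, the receptor of hepatocyte growth factor, was at the floor on the 3 stiff arrays and at least 8.58-fold lower than in distensible aorta (adjusted p = 0.211). NELL2, a secreted protein gene of neural tissue, was at least 8.43-fold lower (adjusted p = 0.282), and BEAN1 at least 4.02-fold lower. CFAP410, a cilium gene, had a mean of 7.54 ± 0.52 in stiff against 11.72 ± 0.86 in distensible aorta (adjusted p = 0.211). HTT, the huntingtin gene, differed by −2.92 ± 0.51 SE and ATXN3, the ataxin 3 gene, by −2.22 ± 0.42 SE. AKAP9, which anchors protein kinase A and other enzymes at the Golgi and centrosome, differed by −2.31 ± 0.44 SE (adjusted p = 0.461). The gut hormone gene PYY, the axonemal dynein gene DNAH9, the pancreatic gene REG1A and the histone demethylase gene KDM5C completed the list, with log2 differences from −2.35 to −2.74. Of the 24 genes named for this comparison, 11 had another tested probe set. For 6 of these, at least 1 such probe set had the opposite sign. Other such probe sets had the same sign but a much smaller difference: −0.68 ± 0.41 SE for MET, −0.74 ± 1.37 for CFAP410 and 0.50 ± 0.98 for MYT1. Of the 24 genes, 8 were at the floor in a whole group. Of the rest, only COMP and KDM5C had no array of the lower class there. For MYT1, MRPS12, PCDH9, VAPB and PTPRD, 3 of the 4 distensible arrays were at the floor. For CFAP410, PYY, HTT and DNAH9, 2 of the 3 stiff arrays were. The sizes and spreads of these differences thus depend on where the floor was set. For many of these genes the higher class also lay below the noise (mean 2304 intensity units on stiff and 2764 on distensible arrays). Stiff arrays stood at 609 to 962 units for MAD2L1 and 471 to 914 for IGF1, and distensible arrays at 890.5 to 1790.5 for MET. In such genes neither class was clear of the noise, so the bound does not set expressed against absent.

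The comparison covered 9270 probe sets. At an unadjusted p under 0.05 there were 404, of which 150 were higher and 254 lower in stiff aorta, against 463.5 that chance gives. Every stiff array lay above every distensible array at 165 probe sets and below at 283, together 4.83% of those tested. Chance gives 5.71% for values without ties. Values set to the floor are tied and lower that share, so 4.83% cannot be said to lie below chance. Arrays of the same class were no more alike than arrays of the other class: the mean correlation across probe sets was 0.747 within and 0.756 between stiff and distensible (exact permutation p = 0.686, one-sided, 35 splits).

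Of the 34 gene lists, 3 were called, all higher in stiff aorta, although many other splits of the arrays called as many. Of the 24 measured genes of the interferon response, 22 had a positive log2 difference, with a median of 0.67 (camera adjusted p = 0.000767, and adjusted p = 0.727 with an estimated correlation). IFIT2 differed by 1.74 ± 0.64 SE, MX2 by 0.69 ± 0.40, GBP1 by 1.47 ± 0.92 and IFITM3 by 0.60 ± 0.38; these genes are induced by interferons and act against viruses and other microbes. Of 18 macrophage markers, 16 were positive, with a median of 1.12 (adjusted p = 0.00751, and adjusted p = 0.825 with an estimated correlation). They included the mannose receptor gene MRC1 (0.94 ± 0.56 SE), the haemoglobin scavenger receptor gene CD163 (1.30 ± 0.80), the Fc receptor gene FCGR3A (1.24 ± 0.78) and CD68 (1.66 ± 1.05). Of 34 inflammatory cytokines and adhesion molecules, 24 were positive, with a median of 0.49 (adjusted p = 0.0148, and adjusted p = 0.727 with an estimated correlation). The chemokines CCL7 (0.85 ± 0.34), CCL19 (2.99 ± 1.37) and CXCL12 (0.89 ± 0.43) were among them, while the cytokine TNF lay on the other side (−0.82 ± 0.35). No single member of these lists passed, either over all genes or adjusted over the list alone, and the lists shared no measured gene.

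None of the 3 calls thus held once the correlation between genes was estimated from these arrays. Per array, the interferon score, the mean log2 value of the members relative to the distensible mean, was 0.64 ± 0.30 (SD, n = 3) in stiff against 0.00 ± 0.41 (SD, n = 4) in distensible aorta (exact permutation p = 0.0571, two-sided, smallest possible 0.0286). The macrophage score varied far more, at 0.95 ± 1.82 against 0.00 ± 1.27 (exact permutation p = 0.429), since stiff replicates 2 and 3 stood at 2.12 and 1.88 and stiff replicate 4 at −1.15. The cytokine score was 0.52 ± 0.49 against 0.00 ± 0.41 (exact permutation p = 0.229). Without stiff replicate 3 no list was called (interferon 0.0697, macrophage 0.234, cytokines 0.251). The macrophage call also ended without stiff replicate 2 (0.436) and both it and the cytokine call without distensible replicate 4 (0.278 for each), and no list was called in the fit of all 10 samples.

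**Figure D1:**
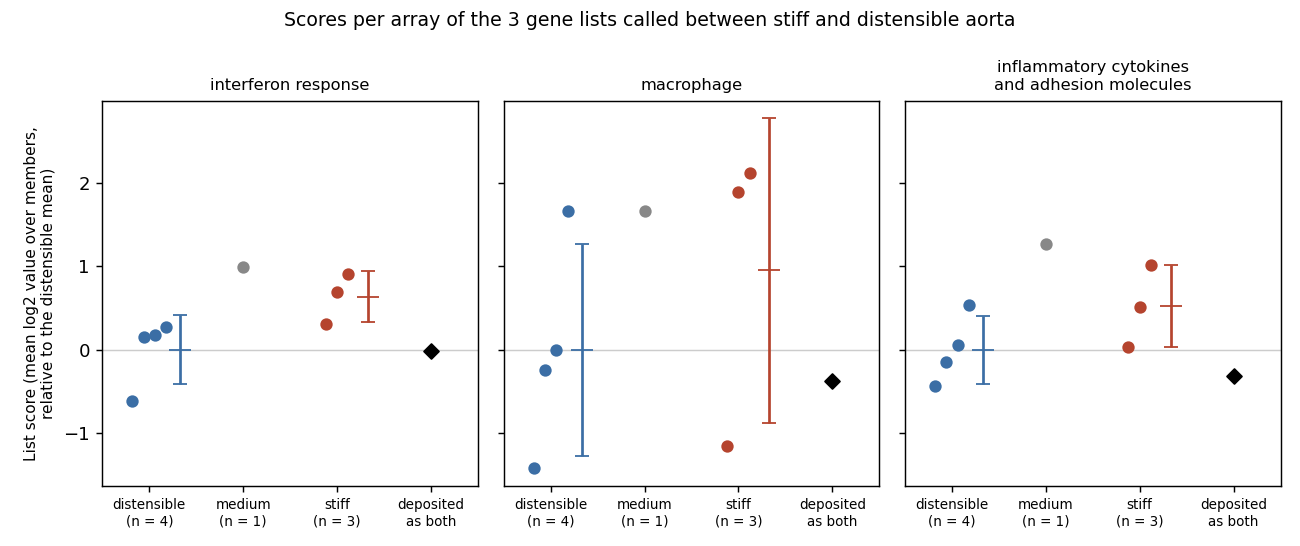
Scores of the 3 called gene lists on each array, as the mean log2 value over a list's measured members relative to the distensible mean (vertical axis, log2 units). Each circle is 1 array, the bar beside a class is its mean ± SD, and the black diamond is the array deposited both as stiff and as medium; the interferon scores of the 3 stiff arrays all lie above those of the 4 distensible arrays, while the macrophage and cytokine scores overlap.

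**Figure D2:**
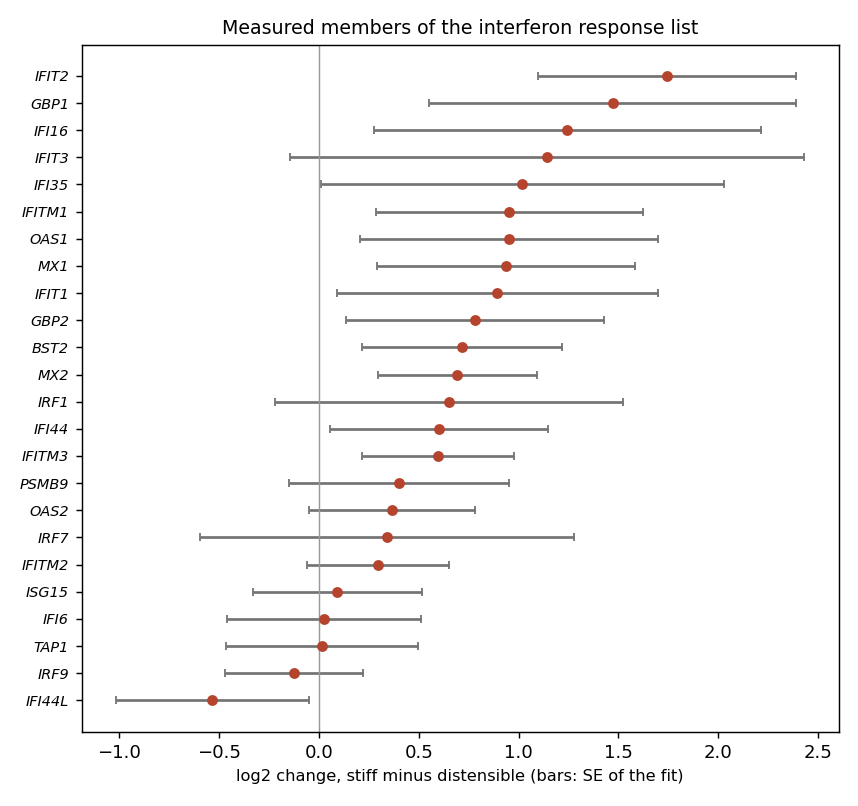
Log2 difference between stiff (n = 3) and distensible aorta (n = 4) (horizontal axis) for each of the 24 measured members of the interferon response list, with the SE of the fit as bars. The points of 22 members lie to the right of 0, from IFIT2 at 1.74 down to TAP1, and IFI44L is lowest at −0.53.

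Among the other cell type markers, the values went both ways and none of the lists was called. Fibroblast markers had a median of 0.81, with 9 of 14 positive (adjusted p = 0.0586), led by the lipocalin APOD (4.17 ± 1.26 SE), the complement gene C7 (1.66 ± 0.50) and lumican, LUM (1.34 ± 0.71). Mesothelial markers had a median of −0.95, with 6 of 7 negative (adjusted p = 0.0586), including the keratin KRT18 (−1.22 ± 0.46), calretinin, CALB2 (−1.06 ± 0.45), and mesothelin, MSLN (−1.91 ± 0.98). Adipocyte markers had a median of 0.41 with 7 of 12 positive (adjusted p = 0.214), and the lipolysis inhibitor gene G0S2 (2.21 ± 0.48) was the 1 member that passed when adjusted over the list alone (0.0264). T and NK cell markers had a median of 0.10 with 9 of 17 positive (adjusted p = 0.913), and CD7 (−2.39 ± 0.61) and CD8A (2.43 ± 0.95) had opposite signs, though neither passed. B and plasma cell markers had a median of −0.03, mast cell markers −0.23 and neutrophil markers 0.09 (adjusted p = 0.913, 0.752 and 0.752). Endothelial markers had a median of 0.23 with 12 of 17 positive (adjusted p = 0.348), platelet markers −0.43 and red blood cell markers −0.73 (adjusted p = 0.314 and 0.555). Markers of cardiac and skeletal muscle had a median of −0.01 and those of nerve and Schwann cells 0.01 (adjusted p = 0.752 and 0.464). The synuclein gene SNCG differed by 2.27 ± 0.71 SE in the nerve list; it was listed with knowledge of the published study, so its direction is not independent evidence.

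**Figure D3:**
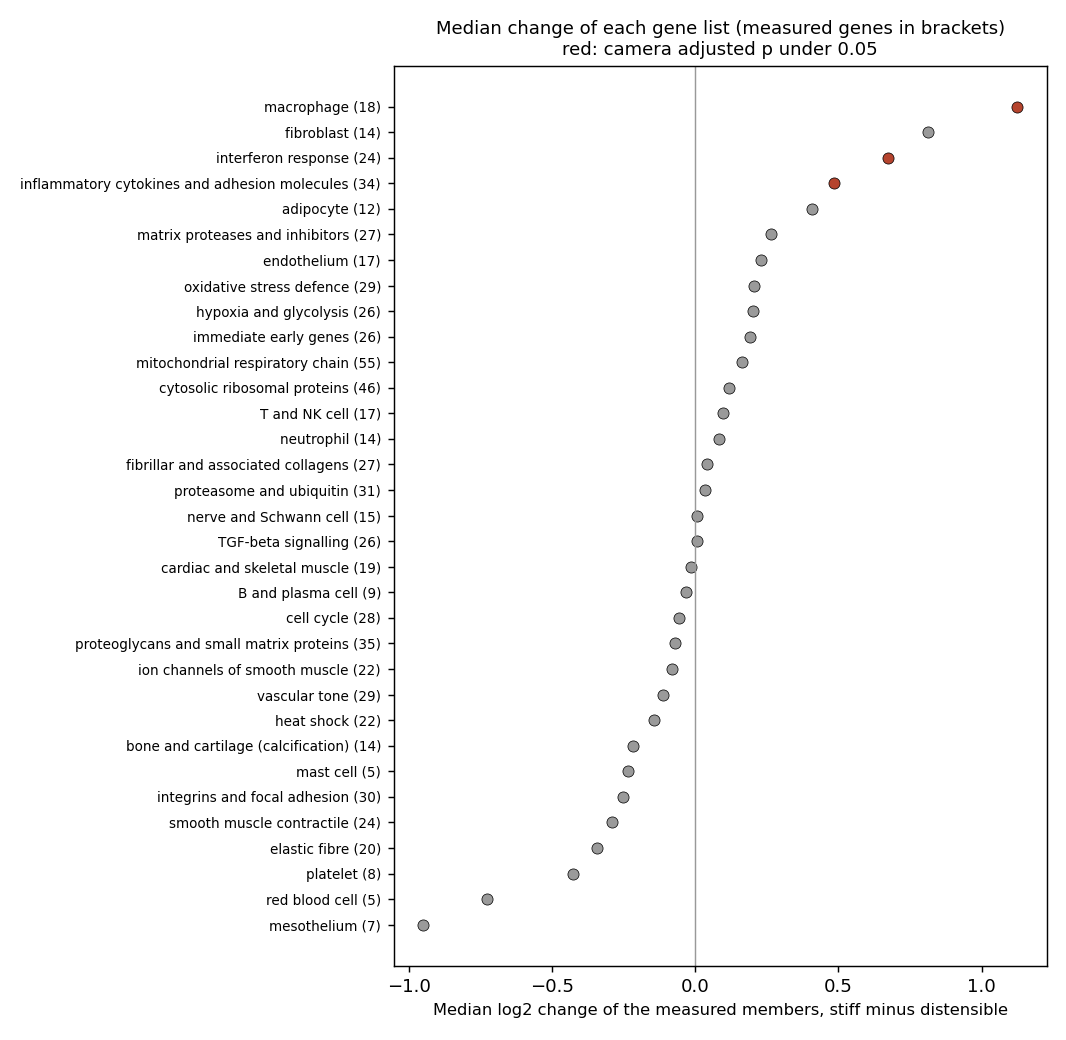
Median log2 difference between stiff (n = 3) and distensible aorta (n = 4) over the measured members of each of 33 gene lists, with the number of measured members in brackets; red points have a camera adjusted p under 0.05. The 3 called lists lie between 0.49 and 1.12, and under median scaling 7 of the 34 tested lists, with medians between −0.11 and −0.01, change sign.

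None of the lists of vessel wall genes was called. The stiff and distensible values of single members such as COL6A3, NID2 and OMD did not overlap, but neither did those of 4.83% of all tested probe sets. Among the collagens this held for 1 of 27 genes, and among the proteoglycans for 1 higher and 2 lower of 35. Of 24 smooth muscle contractile genes, 22 had a negative difference with a median of −0.29 (adjusted p = 0.220), among them caldesmon, CALD1 (−0.72 ± 0.54 SE), and leiomodin, LMOD1 (−0.47 ± 0.39). Of 20 elastic fibre genes 14 were negative, with a median of −0.34 (adjusted p = 0.464): elastin, ELN, differed by −1.27 ± 0.72 and EMILIN1, which joins elastin to microfibrils, by 2.32 ± 0.91. Collagens and their processing enzymes had a median of 0.04 with 14 of 27 positive (adjusted p = 0.367), COL6A3 at 1.04 ± 0.38 being the member with the smallest p. Proteoglycans and small matrix proteins had a median of −0.07 (15 of 35 positive, adjusted p = 0.833), with the basement membrane gene NID2 at −1.36 ± 0.51, osteomodulin, OMD, at −1.86 ± 0.72 and tenascin C, TNC, at 3.13 ± 1.49. Matrix proteases and inhibitors had a median of 0.27 (14 of 27 positive, adjusted p = 0.752), and integrins and focal adhesion genes one of −0.25 (22 of 30 negative, adjusted p = 0.367), with paxillin, PXN, at −3.80 ± 1.32. Genes of bone and cartilage had a median of −0.22 (adjusted p = 0.913), and osteopontin, SPP1, differed by 4.36 ± 1.78. The lists of integrins and of proteoglycans were drawn up with knowledge of the study published on these samples, so their members are not independent evidence.

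The lists of signalling and tone genes had medians close to 0 over members that went both ways, such as the kinase gene PRKG1 (−1.61 ± 1.28 SE) and angiotensinogen, AGT (1.31 ± 1.18). TGF-beta signalling had a median of 0.01, vascular tone −0.11 and ion channels of smooth muscle −0.08 (adjusted p = 0.913, 0.752 and 0.775).

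Among lists of general cell functions, the mitochondrial respiratory chain had 38 of 55 genes positive with a median of 0.16, and cytosolic ribosomal proteins 41 of 46 with a median of 0.12 (adjusted p = 0.0586 for each). Oxidative stress defence had 22 of 29 positive and a median of 0.21 (adjusted p = 0.0653), led by the metallothionein MT2A (1.73 ± 0.81 SE). Hypoxia and glycolysis had a median of 0.20, immediate early genes 0.19, proteasome and ubiquitin genes 0.04 and heat shock genes −0.14 (adjusted p = 0.367, 0.464, 0.464 and 0.913). Cell cycle genes had a median of −0.05 with 14 of 28 positive (adjusted p = 0.752), and MAD2L1 passed when adjusted over the list alone (0.00382). For cell cycle, T and NK cell, B and plasma cell, TGF-beta and bone lists the median, the mean and the test differed in sign. No list beyond the 3 called passed with the preset correlation, and none of the 34 with an estimated one.

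The share of values at or below 0, a measure of array quality, was lower on every stiff than on every distensible array: 25.4% ± 0.43 (SD, n = 3) on stiff and 28.2% ± 2.44 (SD, n = 4) on distensible arrays (exact permutation p = 0.0571, two-sided). The noise, as the root mean square of the values below 0, was 2304 ± 341 (SD, n = 3) against 2764 ± 811 (SD, n = 4) intensity units (exact permutation p = 0.543). The log2 ratio of the 3' to the 5' control probe sets, which rises as RNA breaks down, was 2.23 ± 0.77 against 1.69 ± 0.27 for GAPDH and 2.45 ± 0.68 against 2.08 ± 0.40 for actin (exact permutation p = 0.257 for GAPDH and 0.4 for actin). Distensible replicate 3 stood apart, with 31.8% of values at or below 0 and a mean correlation of 0.707 with the other arrays. Stiff replicate 2, which had the highest interferon and macrophage scores of the stiff arrays, also had the highest 3' to 5' log2 ratios (3.01 for GAPDH and 3.10 for actin); without it the interferon list was still called at the preset correlation (adjusted p = 0.0286) and the macrophage list was not (0.436). On all arrays the interferon list had an adjusted p = 0.727 with an estimated correlation.

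The medium class was compared with both ends through its 1 remaining array, which was assumed to vary like the arrays of the other classes. No probe set passed in limma against distensible aorta (233 at an unadjusted p under 0.05, where chance gives 463.5) or against stiff aorta (153). The genes with the smallest p on the lower side of medium against distensible were TBC1D5, the T cell costimulator ICOS, the inhibin subunit INHBC, FMO6P and the transcription factor NFIA, all at the floor on the medium array and so at least 15.1-fold lower for TBC1D5, at least 15.7-fold for INHBC and at least 12.8-fold for NFIA (adjusted p = 0.546 for each). DYRK4, MYT1, G0S2, TADA2A and TBKBP1 stood on the higher side, with differences from 2.88 to 4.04. DYRK4 was at the floor on all 4 distensible arrays, so its difference is at least 3.05. Each of the others was at the floor on 3 of the 4 distensible arrays. On the higher side of stiff against medium, the medium array was at the floor for all 5 genes named. The stiff mean was at least 43.6-fold higher at 1 probe set of COMP, but another COMP probe set differed by 2.93 ± 1.16 SE. It was at least 10.6-fold higher for TBC1D5 and at least 9.66-fold at 1 probe set of the interleukin receptor IL9R, of which another had the opposite sign (−0.70 ± 1.07 SE), and ICOS and INHBC were named again. KIF17, at the floor on the stiff arrays, was at least 18.9-fold lower in stiff than in medium aorta (adjusted p = 0.360). Next on this side, each with an adjusted p of 1, were the peptide hormone gene UCN (at least 19.3-fold), DYRK4 (log2 difference −1.94 ± 0.50 SE), BEAN1 (at least 3.93-fold) and the growth factor gene FLT3LG (at least 6.38-fold). Without a filter on dim probe sets, 65 and 63 probe sets were called, of which 44 in each case were above the floor on the medium array alone.

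A trend over the classes, scored 0, 1 and 2 from distensible to stiff, called no probe set in limma (468 at an unadjusted p under 0.05, where chance gives 463.5). The largest evidence for a rise with stiffness was at MRPS12, a mitochondrial ribosomal protein gene (1.60 ± 0.20 SE per class, adjusted p = 0.248), followed by MAD2L1, IGF1, ACAT1 and PCDH9. Other probe sets of MRPS12 (−0.07 ± 0.16), IGF1 (−0.84 ± 0.43) and PCDH9 (−0.61 ± 0.29) had the opposite sign, as did that of ATXN3 among the falling genes. On the falling side stood KIF17 (−2.14 ± 0.30, adjusted p = 0.248), NELL2, MET, ATXN3 and CFAP410. Equal steps between classes were assumed, since the labels give no pulse wave velocity. Without medium replicate 2 the trend is the comparison of stiff with distensible aorta itself, so it called KIF17 again (adjusted p = 0.0224).

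On the 100 genes that best separated stiff from distensible aorta, the medium array lay at a median position of 0.691 on a scale from 0 (distensible mean) to 1 (stiff mean). For 100 genes drawn at random 1000 times the median position was 0.742, with a central range of the draws from 0.478 to 1.01, so the position among the selected genes did not differ from that of the array as a whole. Without stiff replicate 2, 3 or 4 it was 0.321, 0.469 and 0.316. When each stiff or distensible array was held out of the selection in turn, the held-out stiff arrays stood at 0.369 ± 0.116 (SD, n = 3) and the held-out distensible arrays at 0.706 ± 0.0884 (SD, n = 4). Holding an array out moves the mean of its own class away from it, so this order is no evidence of a reversal, but the selected genes did not place held-out arrays nearer to their own class.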

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

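The tests on the asinh scale, with an estimated correlation, among probe sets above the floor on every array, of the macrophage score less the T and NK cell score, and of pairs of cell type lists were chosen after the results they bear on had been seen. Only the distensible class, the largest, was tested for a sample far from the others. In it, 74 sets of values were tested. Of these, 12 had a gap that filled more of the range than the critical value for 4 arrays, where chance gives about 5%. In 8 genes the gap was the whole range (1), because 3 distensible arrays were at the floor. Distensible replicate 2 stood above it for MYT1, MRPS12, PCDH9, VAPB and PTPRD, at log2 values from 7.90 to 8.46, and distensible replicate 1 for G0S2, TADA2A and TBKBP1, the last at 7.52. For INHBC, distensible replicate 1 stood at 10.54 against 11.33 to 11.48 on the others (0.837 of the range). The interferon score of distensible replicate 3 was −0.61 against 0.16 to 0.28 on the others (0.866), and its smooth muscle contractile score was 0.35 against −0.14 to −0.07 (0.851). The hypoxia and glycolysis score of distensible replicate 4 was −0.26 against 0.06 to 0.12 (0.835).

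The interferon, macrophage and cytokine lists were higher in stiff aorta, and chance cannot be excluded for the number of lists: 13 of the 35 splits of the 7 arrays called as many as the real split (3), and the highest other split called 9. Among probe sets above the floor on every array, the interferon list kept 17 of 24 genes, a median of 0.60 and a camera adjusted p of 0.00156. The cytokine list kept 17 of 34 genes, a median of 0.23 against 0.49 and an adjusted p of 0.0415. The macrophage list kept 13 of 18 genes, a median of 0.94 against 1.12 and an adjusted p of 0.00156. All 3 calls thus held without members at the floor, in a test at the preset correlation. That correlation may be too low and the floor lies below the noise, so this test cannot exclude dim members as a cause. Correlation between the genes of a list remains open as a cause. With an estimated correlation the camera adjusted p was 0.727 for the interferon list, 0.727 for the cytokine list and 0.825 for the macrophage list. The mean difference of the interferon list was 0.64 in both tests, so its call ended through a wider error and not a smaller difference. A lower share of smooth muscle, which would raise all other cell types alike, cannot be told apart from a change in macrophages, because the macrophage score less the T and NK cell score was higher by 0.92 in stiff (n = 3) than in distensible aorta (n = 4) (exact permutation p = 0.257, two-sided). Fibroblast less mesothelial scores did part the classes, by 1.45, but this is 1 of 78 pairs of cell type lists, of which 10 parted the classes, and 3 of the 35 splits parted as many (highest other split 18). A difference between stiff and distensible aorta also stays open, untested beyond these arrays.

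KIF17 was the 1 gene called between stiff and distensible aorta, and 9 of the 35 splits called at least as many probe sets (real value 1, highest other split 18), so chance cannot be excluded. The floor may have made the call: on the asinh scale, which has none, the difference was −1.21 ± 0.18 SE against −4.36 ± 0.34 SE in log2 units with the floor, and the adjusted p 0.968 against 0.0224. The 2 differences cannot be compared in size, since the asinh scale compresses values as low as these, and the floor gives all 3 stiff arrays 1 value and so no spread. The split with 18 calls set stiff replicates 2 and 3 and distensible replicate 1 against the other 4 arrays. It also called 9 lists, which points to a structure of the arrays. None was tested, and this split was the highest of 34 others. The macrophage scores of stiff replicates 2 and 3 and distensible replicate 1 were 2.12, 1.88 and 1.66. On the other 4 arrays they lay between −1.42 and 0.00. The macrophage scores thus parted along this split, which crosses the classes, while those of stiff and distensible aorta overlapped. The macrophage call may therefore reflect this grouping of the arrays and not the class, which was not tested. A biological difference in KIF17 stays open, untested.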

How the results depend on the processing

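The fits with the array deposited under 2 classes and the asinh scale were chosen after the data were seen; where no cause is given below, the cause was not tested. Nothing reversed: the 3 called lists stayed higher in stiff aorta and the named genes kept their sign under every alternative that could be run. The genes named for stiff against distensible aorta had been chosen for values that did not overlap. Their sign could thus hardly turn, and its constancy is no evidence for them. Of the named genes in stiff against distensible aorta, 449 values kept their side of the threshold, 13 lost it (all KIF17) and 2 gained it; in the medium comparisons 4 and 4 gained it and in the trend 1. A floor at the 10th percentile was not run, since that percentile is negative (−958.85). No paired analysis was possible because the replicate numbers follow the order of deposit and pair nothing.

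For stiff against distensible, 0 probe sets were called with a floor at the 50th percentile, above the floor on every array, with variance trend and robust eBayes, with stiff replicates 1 and 4 averaged, with the array under 2 classes counted as stiff, and on the asinh scale. Stiff replicate 1 is the array under 2 classes, so the averaging also put that array among the stiff ones. The fit of all 10 samples did so too, so these settings are not independent of each other. All 10 samples as first designed called 2 (MYT1 higher, CFAP410 lower). Leaving out each array gave 0 to 1. For medium against distensible, no filter on dim probe sets called 65 (60 higher, 5 lower), 59 of them untested with the filter, and variance trend and robust eBayes called 1, which has no single symbol. For stiff against medium, no filter called 63 (3 higher, 60 lower), and counting the array as medium called 1 (KIF17). The trend called 0 to 1 with arrays left out, the 1 being KIF17 without the medium array, where the trend is the comparison of stiff with distensible.

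The number of called lists was 6 with median scaling (5 higher, 1 lower), 6 with the 50th percentile floor, 7 above the floor on every array, 8 with variance trend and robust eBayes, 5 with stiff replicates 1 and 4 averaged and 8 on the asinh scale. It was 0 with all 10 samples, with the array counted as stiff, with an estimated correlation and with fry, and 0 to 6 with arrays left out. Median scaling moved the median log2 difference of all probe sets by 0.13 and turned the sign of 7 list medians; quantile normalization turned 3. The interferon list had an adjusted p of 0.0582 with all 10 samples, 0.0535 with the array as stiff, 0.727 with an estimated correlation and 0.678 with fry, and 0.000295 to 0.0697 with arrays left out. The macrophage list had 0.0582, 0.0535, 0.825 and 0.678 in the same order, and 2.15e-08 to 0.436. The list of inflammatory cytokines and adhesion molecules had 0.344, 0.175, 0.727 and 0.678, then 0.0601 with no filter on dim probe sets, 0.0533 with the array under 2 groups counted as medium, and 0.000404 to 0.278 with arrays left out. The medium array's position was 0.569 on 200 genes, and 0.316 to 0.664 with arrays left out.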

Other observations

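The 4 gene lists below were chosen after the macrophage and interferon lists had been seen and before their own values were; their tests rest on the same arrays. Lysosomal genes, which break down what macrophages and other cells take up, were higher in stiff aorta, with 26 of 32 positive and a median log2 difference of 0.44 (camera adjusted p = 0.00333 over the 4 lists, and adjusted p = 0.45 with an estimated correlation). The hexosaminidase gene HEXA differed by 1.09 ± 0.47 SE, the peptidase gene TPP1 by 1.11 ± 0.71 and the cholesterol transporter gene NPC1 by 0.86 ± 0.56, while the cathepsin gene CTSB lay at −0.57 ± 0.67. Complement genes had 10 of 15 positive and a median of 0.51 (adjusted p = 0.0383, and adjusted p = 0.45 with an estimated correlation), with C7 at 1.66 ± 0.50, C1R at 1.17 ± 0.55 and C1S at 0.81 ± 0.39, but C6 at −1.60 ± 0.91. Each of these lists shared 1 gene with the macrophage list, and the complement genes C7 and CFD are also in the fibroblast list, so the complement value is no evidence for phagocytes in particular. For genes of MHC class II, 11 of 12 were positive with a median of 0.58 (adjusted p = 0.0609), and for those of MHC class I 10 of 12 with a median of 0.22 (adjusted p = 0.0815), so these tests left the matter open.

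The other 2 lists also had an adjusted p of 0.45 with an estimated correlation, and exact permutation p-values of the 4 scores lay between 0.229 and 0.571 (two-sided, 3 against 4 arrays). The hypothesis that phagocyte genes beyond the listed markers are higher in stiff aorta is thus consistent with the lysosome value of 0.00333 under the preset correlation only. On the medium array the lysosome score was 0.70 and the MHC class I score 0.55.

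The array deposited both as stiff and as medium entered none of the main comparisons. Its interferon score was −0.01, its macrophage score −0.37 and its cytokine score −0.31. On the other medium array these scores were 0.996, 1.67 and 1.27. There the interferon and cytokine scores exceeded those of every stiff array in the main fit (highest 0.907 and 1.01). The macrophage score lay between those of stiff replicates 3 and 4. The interferon and cytokine scores were thus highest on a medium array, and whether they follow stiffness was not tested. The smooth muscle contractile score of the array deposited under both classes was 0.59 and its platelet score −1.10. On the 100 genes that separate stiff from distensible aorta it stood at 0.665, where random genes gave 0.480 with a central range of the draws from 0.140 to 0.818.

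The macrophage score was 1.66 on distensible replicate 1, close to stiff replicates 2 and 3 (2.12 and 1.88), and −1.42 on distensible replicate 4, close to stiff replicate 4 (−1.15). Of the 35 splits of the 7 arrays, 24 called at least 1 list, and 19 gave as many probe sets at an unadjusted p under 0.05 as the 404 of the real split, the highest of the others being 889. The unadjusted camera p of the interferon list was smallest in the real split (2.26e-05), but 2 other splits came close (3.52e-05 and 6.16e-05).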
